A study of Rattus norvegicus with 7 samples.

How the data were processed

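Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in A10 cells, a rat vascular smooth muscle line from the thoracic aorta, with antibodies against Arteridin and against the nucleic acid binding protein YBX1. Per the labels, the Arteridin libraries were read as single-end reads of 50 nt and the YBX1 libraries as paired-end reads of 150 nt. The 7 libraries comprised 2 Arteridin ChIP libraries, 3 YBX1 ChIP libraries and 2 inputs, with 1 library per condition. Groups were taken from the sample titles. ORF was read as Arteridin overexpression and CTR as the Arteridin ChIP without it; ART and PSR were read as YBX1 ChIP with overexpression of tagged Arteridin and of the start-codon mutant of the long non-coding transcript lncPSR. The YBX1 library labelled NC was matched to the untreated condition because the design text names 3 YBX1 conditions and the other libraries took the rest. Titles of ART and PSR begin with another letter than those of NC and the YBX1 input, and the labels do not say what the letter marks.

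The authors deposited 1 peak list per ChIP library, narrow peaks for Arteridin and broad peaks for YBX1, and no list pooled libraries. Per the submitters' processing notes, FastQC, Bowtie2, SAMtools, MACS2 and HOMER were used, and versions, cutoffs and duplicate handling are not given in the sources used here. The genome build is not given in the sources used here either; the sequence names of the deposited lists are those of the rat assembly Rnor_6.0. Coordinates are given as in the lists, counted from 1. Each deposited row holds a score, a fold enrichment over the expected level (a ratio), and −log10 p and −log10 q values, all computed by the authors' peak caller. The deposited score was the whole part of 10 times the −log10 q value. Deposited narrow peaks also give the other value of the format, the distance of the summit from the peak start. Fold and −log10 q are the authors' own values for each peak and were used only to describe, rank or filter peaks within a list.

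Peak lists were compared by overlap of at least 1 bp, and the counts were recomputed with bedtools 2.31.1 with the same result. Shares carry 95% Wilson intervals, which cover counting error only. Chance overlap was taken from 1000 random placements of the peaks of one list on their own chromosomes, with lengths kept, on chromosomes 1 to 20, X and Y. Chromosome ends were set at the furthest listed peak end. The labels show 1 input library per antibody. If the lists of an antibody were called against it, part of any excess over random placement comes from that shared input. Lists of different antibodies name unplaced scaffolds differently and were compared on the assembled chromosomes. Dense segments were found by linking peaks of the 2 Arteridin lists over gaps of up to 100 kb and keeping segments with at least 20 peaks; for YBX1 the ART and PSR lists were linked and at least 10 peaks were required. The segments were defined after the lists had been seen.

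The lists give no read counts. For narrow peaks, the number of reads at the summit and the expected level were recovered by solving the 2 relations that MACS2 uses, in which fold is (reads + 1) over (expected level + 1) and p is the Poisson probability of more reads than observed. A whole number of reads met both values within 0.0001 in −log10 p for all 3013 ORF and 2079 CTR peaks. Broad peaks carry averages over the region, and 20 NC, 26 ART and 14 PSR peaks could be solved. The lowest expected level solved in a list was taken as its genome background, which grows with the number of reads and the fragment length. Arteridin levels above the background recurred at 1 most common step, taken as the worth of 1 input read, and the ratio of these steps, 1.02, was used to correct ORF over CTR read ratios for depth. Of the ORF and CTR levels above the background in the chromosome 6 segments, 72.3% and 74.9% were whole multiples (within 0.0001) of the worth of 1 input read spread over 10 kb, with the shortest peak of a list as fragment length, against 4.02% and 4.16% by chance. The expected level at a peak was accordingly taken as no lower than the input average over 10 kb around it, as in the caller. On simulated data the solution returned the right number of reads for 100% of 1915 peaks, and 0.052% of simulated peaks with mismatched values gave a false match. In a simulation with CTR peak lengths, 205 overlaps were found where 200 were planted among 1971 peaks, and 2 where none was planted. Simulated positions were spread evenly along each chromosome. The simulation therefore checks the counting and not chance overlap within dense segments.

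Named peaks were chosen before the data were examined: for each pair of lists, up to 8 shared peaks and up to 8 peaks of each list alone with the highest fold on assembled chromosomes, and YBX1 regions present in all 3 lists. Peaks outside this rule are said to have been chosen after their values were seen. The alternatives were stricter thresholds (−log10 q of at least 5, fold of at least 4), assembled chromosomes only, merging within 1000 bp, reciprocal overlap of 50%, centres within 1000 bp (the summit of a narrow peak, the midpoint of a broad one), removal of clusters of 3 or more peaks within 10 kb, and random placement within 1 Mb. For overlaps, peaks were filtered in both lists of a pair, so a peak that overlapped only removed peaks counted as not overlapping. With 1 library per condition there was no replicate check, and no p-value was computed across peaks. Gene annotation of the peaks, the fixed gene lists, motifs and repeat content had been planned and were not made, because no annotation or sequence of the lists' assembly was used here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.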

Results

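Arteridin is a coding product of the Phenotype Switching Regulator gene, whose non-coding product is lncPSR, and YBX1 is a DNA- and RNA-binding protein. The series asked where Arteridin sits on chromatin in A10 smooth muscle cells with and without its overexpression, and where YBX1 sits in cells labelled NC, in cells overexpressing Arteridin (ART) and in cells overexpressing a start-codon mutant of lncPSR (PSR). Each condition had 1 library, so differences between conditions have no replicate check. Arteridin ChIP gave 3013 narrow peaks with overexpression (ORF) and 2079 without (CTR), with median lengths of 81 and 79 bp, covering 299.2 and 195.1 kb. YBX1 ChIP gave 608 broad peaks in ART, 341 in PSR and 82 in NC, with median lengths of 398.5, 370.0 and 285.5 bp, covering 422.6, 197.3 and 27.6 kb.

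Most listed peaks were weak. The authors' median fold enrichment was 5.63 in ORF, 5.66 in CTR, 4.41 in ART, 4.46 in PSR and 3.81 in NC. A −log10 q of at least 5 was reached by 488 ORF, 316 CTR, 56 ART, 29 PSR and 6 NC peaks. The median Arteridin peak had 8 reads at its summit in both lists. The genome background level per position was 0.361 in ORF and 0.349 in CTR, a ratio of 1.03, whereas ORF held 1.45 times as many peaks. Among the YBX1 lists the background was 0.362 in ART, 0.380 in PSR and 0.048 in NC, so NC lay 7.54 times below ART and 7.91 times below PSR. Among the peaks whose reads could be recovered at the background level, the lowest had 3 reads in NC and 5 in ART and in PSR. Differences in peak number between NC and the overexpression libraries therefore go with a difference in background.

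**Figure D1:**
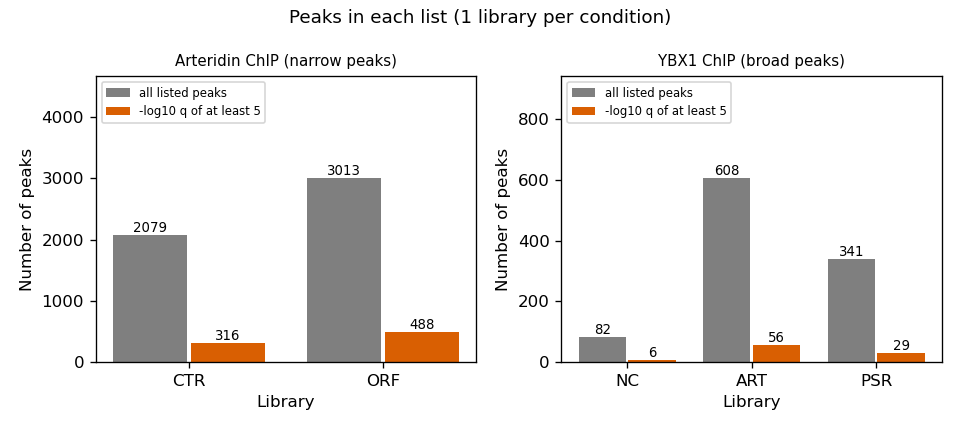
Number of listed peaks per library (grey) and number with a −log10 q of at least 5 (orange), with Arteridin ChIP on the left and YBX1 ChIP on the right. ORF held 3013 peaks and CTR 2079, and ART held 608, PSR 341 and NC 82, and stronger peaks were a minority in each list.

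Arteridin peaks were concentrated at the start of chromosome 6, with and without overexpression. Of the ORF peaks, 2566 (85.2%, 95% interval 83.9 to 86.4) lay in 6 segments between positions 8524 and 11720206, and so did 1753 of the CTR peaks (84.3%, 82.7 to 85.8). The segments cover 8.04 Mb, 0.297% of the summed chromosome length. The longest, 6462222 to 9981205, held 1157 ORF and 777 CTR peaks. The densest, 2809159 to 3787697, had 55.3 ORF and 41.1 CTR peaks per 100 kb. Between 4883978 and 5666887 the density fell to 11.1 and 7.92 peaks per 100 kb. YBX1 peaks showed no such concentration, with 3 ART, 1 PSR and 1 NC peak in the same segments, which is 0.493%, 0.293% and 1.22% of each list. The expected level at the summits in the segments, taken from the input where it exceeded the background, had a median of 0.478 in ORF and 0.443 in CTR, which is 1.32 and 1.27 times the genome background.

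**Figure D2:**
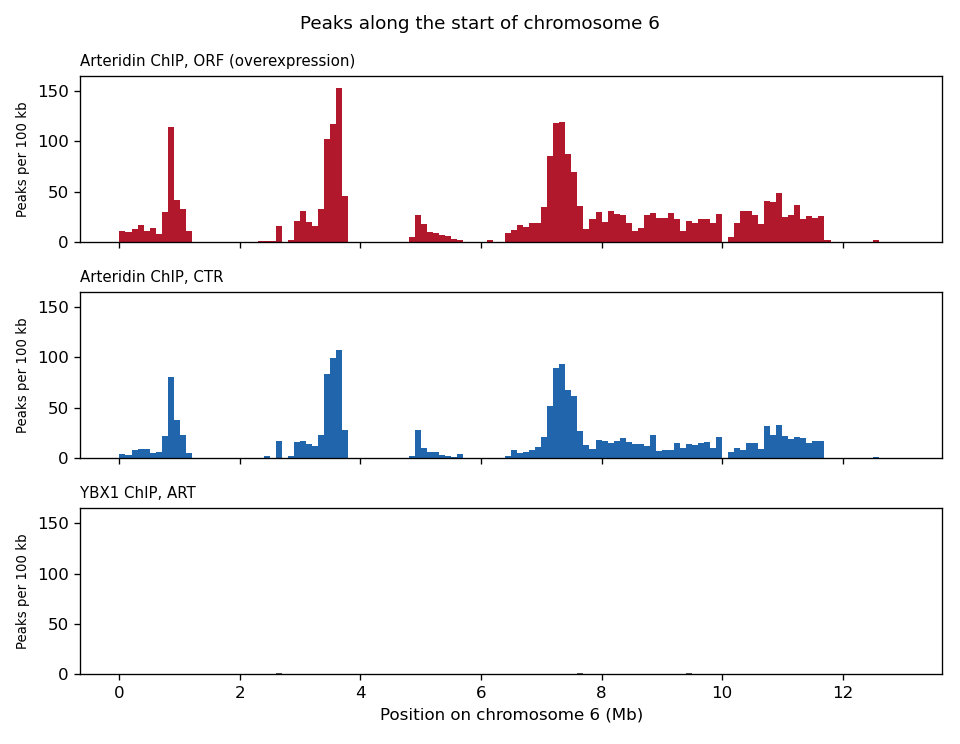
Peaks per 100 kb (vertical axis) along the start of chromosome 6 in Mb (horizontal axis) for Arteridin ORF, Arteridin CTR and YBX1 ART, on 1 scale. Both Arteridin lists rise to their highest bins at 3.6 Mb, with 153 and 107 peaks, and ART has 3 peaks in the Arteridin segments.

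Outside chromosome 6 few regions held dense Arteridin peaks, and most of them were alike in both lists. A region on chromosome 1 from 228985925 to 229025465 held 32 peaks in each list, and one on chromosome 15 from 22207484 to 22212120 held 11 in each. A region on chromosome 2 from 197333140 to 197349226 held 12 ORF and 11 CTR peaks. The exception was chromosome 8 from 38745992 to 39044283, with 26 ORF and 9 CTR peaks. The mitochondrial genome held 27 ORF and 25 CTR peaks of low fold (medians 2.16 and 2.18), where the expected level was 31.4 and 30.5.

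With overexpression, the positions of single Arteridin peaks overlapped those without it in part. Of the CTR peaks, 690 (33.2%, 31.2 to 35.2) overlapped an ORF peak, and 680 ORF peaks (22.6%, 21.1 to 24.1) overlapped a CTR peak. On the assembled chromosomes 620 CTR peaks overlapped, against a mean of 5.87 after random placement on the chromosome, 92.9 within 1 Mb and, in an alternative added after the data were seen, 291.4 within 5 kb. Inside the chromosome 6 segments 532 of 2566 ORF peaks (20.7%) overlapped CTR, 1.96 times the mean within 5 kb. On other assembled sequence 79 of 356 (22.2%) did, 4.95 times that mean. The summits of 71.6% of CTR peaks lay within 1000 bp of an ORF summit. No random placement was made for this distance. With up to 153 ORF peaks per 100 kb in the segments, much of this nearness can come from density alone. With clustered peaks removed from both lists the overlapping share of CTR fell to 9.38%.

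The shared Arteridin peaks with the highest fold lay on chromosomes 13 and 1, and most of the 8 highest did not differ in reads beyond counting error, the interval of the ORF over CTR ratio spanning 1 at 5 of them. The highest, chromosome 13 from 75060105 to 75060408, had 106 reads at its summit in ORF and 81 in CTR, a ratio of 1.29 after correction for depth (95% exact binomial interval 0.956 to 1.74). The 106 reads are the most in the ORF list, and duplicate handling is not known. If reads at the same position were counted once, the ORF number may be capped and this ratio too low. Chromosome 1 from 265469348 to 265469424 had 56 and 23 reads, a ratio of 2.40 (1.45 to 4.08). Chromosome 13 from 75060968 to 75061039 had 49 and 24 reads, a ratio of 2.01 (1.21 to 3.43). The strongest shared peaks inside the chromosome 6 segments were 3388147 to 3388595, with 26 and 18 reads, and 11029020 to 11029215, with 47 and 28, the latter a ratio of 1.65 (1.01 to 2.74). Over the 680 shared ORF peaks the median of such ratios was 0.985 and the middle 95% ran from 0.606 to 1.77, among peaks that had passed the caller in both lists. These intervals compare 2 libraries by counting error and not the conditions, and sites were ranked by the ORF fold, which favours higher ORF values.

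Peaks listed with overexpression alone were of modest height. The 8 highest had folds of 9.50 to 12.4 and 6 of them lay in the chromosome 6 segments. The first was 9573244 to 9573311 with 23 reads, followed by 9574426 to 9574584 with 22 and 7699440 to 7699499 with 21. Outside chromosome 6, chromosome 5 from 142610452 to 142610507 had 13 reads against an expected 0.383. The 8 highest CTR-only peaks had folds of 8.80 to 10.0, and 7 of them lay in the segments, led by 10919858 to 10920011 with 13 reads. A peak missing from one list has no value there, so absence was not measured.

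YBX1 peaks in ART and PSR cells overlapped in part, and most PSR peaks with a −log10 q of at least 5 were also in ART. Of the PSR peaks, 105 (30.8%, 26.1 to 35.9) overlapped an ART peak, and 99 ART peaks (16.3%, 13.6 to 19.4) overlapped a PSR peak. On the assembled chromosomes 99 PSR peaks overlapped, against a mean of 0.121 after random placement on the chromosome, 1.66 within 1 Mb and 40.7 within 5 kb. Among peaks with a −log10 q of at least 5, 27 of 29 PSR peaks (93.1%, 78.0 to 98.1) overlapped ART and 27 of 56 ART peaks (48.2%, 35.7 to 61.0) overlapped PSR. That filter lowered the median fold to 1.91 in PSR and 2.69 in ART, so the filter kept mainly peaks of low fold. A low fold reaches such a −log10 q only where the expected level is high, so a shared input may bear on this overlap. Shared ART peaks were longer than unshared ones, with a median of 847 against 364 bp, and had lower folds, 3.02 against 4.46. Their median −log10 q was higher, 4.25 against 2.02. Dense blocks, 6 in number, held 86 ART peaks (14.1%) and 54 PSR peaks (15.8%). The block with the most peaks, chromosome 14 from 46517738 to 46685841, had 30 ART and 20 PSR peaks and no NC peak. Chromosome 1 from 11904153 to 11974907 had 14 and 10.

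**Figure D3:**
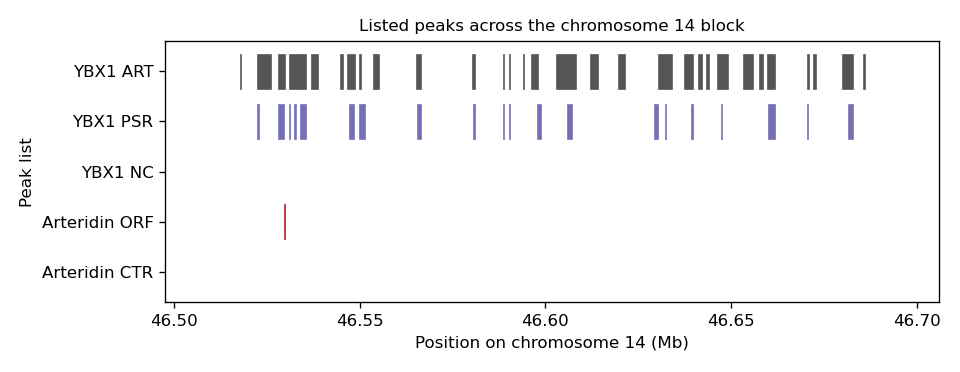
Listed peaks (bars, to scale) along chromosome 14 in Mb (horizontal axis) for each of the 5 lists (vertical axis). ART has 30 peaks in the block, PSR 20, Arteridin ORF 1, and NC and CTR have none.

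The rankings in this paragraph are for assembled chromosomes. Scaffold regions shared by ART and PSR had higher ART folds, 28.4 to 30.6. The shared ART and PSR peaks with the highest ART fold were chromosome 6 from 9464648 to 9465060 (12.7), chromosome 10 from 84915178 to 84915868 (11.2) and chromosome 20 from 4368704 to 4369054 (10.2). The ART-only peaks were led by chromosome 1 from 162984532 to 162985110 (8.21), chromosome 4 from 157607261 to 157608143 (8.08) and chromosome 5 from 173429485 to 173430362 (7.27). The PSR-only peaks were led by chromosome 9 from 61668500 to 61668855 (6.73), chromosome 1 from 138299963 to 138300258 (6.53) and chromosome 7 from 768615 to 768911 (6.42). The 8 highest ART-only peaks had −log10 q values of 4.04 to 8.06, and the 8 highest PSR-only peaks 3.51 to 5.02.

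Few YBX1 peaks of the NC list were found with overexpression, but these included most of its strong ones. Of the 82 NC peaks, 9 overlapped ART and 9 overlapped PSR (10.98%, 5.88 to 19.6 in each case). On the assembled chromosomes 6 overlapped each, against means of 0.021 and 0.016 after random placement on the chromosome and 0.859 and 0.840 within 5 kb. Of the 6 NC peaks with a −log10 q of at least 5, 5 overlapped a peak of ART or PSR (83.3%, 43.6 to 96.99). Only 2 of these 5 lay on assembled chromosomes. Of the 62 with a −log10 q under 2, 1 overlapped either list. A single −log10 q, 1.40, was shared by 48 of the 82 NC peaks, close to the lowest of the list, 1.34. The 20 NC peaks whose reads could be recovered had 3 reads each. The low overlap therefore largely describes weak calls and does not show different sites. Among 914 merged YBX1 regions, 8 were in all 3 lists, 89 in ART and PSR, 508 in ART alone, 235 in PSR alone and 72 in NC alone.

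Of the 8 YBX1 regions in all 3 lists, 5 lay on assembled chromosomes and 3 on unplaced scaffolds. On assembled chromosomes, chromosome 6 from 9464648 to 9465087 had a fold of 7.32 in NC, 12.7 in ART and 14.02 in PSR. Chromosome 10 from 84915178 to 84915876 had 6.70, 11.2 and 12.6, and chromosome 7 from 3123313 to 3123793 had 6.21, 6.95 and 7.29. Chromosome 1 from 180893097 to 180893589 and chromosome 13 from 33502454 to 33505200 had folds of 1.59 to 2.09 in the 3 lists. The scaffold regions had folds of 60.9 to 69.1 in NC and 26.5 to 38.6 in ART and PSR. Folds of different lists depend on the background of each and show no change between conditions.

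The strongest NC peak was not listed in ART or PSR. It lay on chromosome 1 from 265469321 to 265469626, with a fold of 88.2 and a −log10 q of 815.2. It covered the Arteridin peaks described above at that site, whose folds were 36.8 in ORF and 15.7 in CTR. The reads and expected level of this NC peak could not be recovered, so whether the YBX1 input was raised there is not known. The next NC peak absent from ART and PSR, chromosome 1 from 251614041 to 251614330, had a fold of 5.76.

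Arteridin and YBX1 peaks seldom coincided. Of 914 merged YBX1 regions, 8 (0.875%, 0.444 to 1.72) overlapped an Arteridin peak of either list, against a mean of 0.745 after random placement on the chromosome. Within 5 kb of the regions' own positions random placement gave 4.38 on average, with a 95% range of 1 to 8. The observed 8 lay at the upper edge of that range. Such placements can also return a region to its own site, so they cannot show what the neighbourhood alone gives. ART overlapped ORF at 7 peaks and CTR at 4, PSR overlapped ORF at 2 and CTR at 1, and NC overlapped each at 1. Of the ORF peaks shared with ART, the highest fold was at chromosome 15 from 22207819 to 22207871 (8.08), where ART had a fold of 2.46. Chromosome 1 from 148166768 to 148166846 had a fold of 5.14 at the background level. Chromosome 6 had shared peaks from 2672070 to 2672414 (4.76), 2672478 to 2672842 (4.04) and 30644104 to 30644176 (2.47), and chromosome X one from 359726 to 359860 (4.41). Chromosome 1 from 148643495 to 148643570 and chromosome 14 from 46529825 to 46529907 had folds of 2.46 and 2.27, with expected levels of 22.5 and 19.7. With a −log10 q of at least 5 in both lists, no ART or PSR peak overlapped an Arteridin peak, where random placement gave means of 0.001 to 0.006.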

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

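Alternatives named as added were chosen after the data were seen; the others were fixed before the data were examined. With a −log10 q of at least 5, the lists held 488 (ORF), 316 (CTR), 56 (ART), 29 (PSR) and 6 (NC) peaks. A fold of at least 4 left 21 NC peaks. Merging within 1000 bp left 1648 ORF and 1203 CTR peaks. In added alternatives, a −log10 q of at least 2 left 359 ART, 177 PSR and 20 NC peaks, and removal of the chromosome 6 segments left 447 ORF and 326 CTR peaks. The order ART, PSR, NC and ORF over CTR held in all of these.

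The share of ORF peaks in the chromosome 6 segments was 79.9% at the stricter −log10 q, 87.5% at the stricter fold, 87.8% on assembled chromosomes and 81.9% after merging. The CTR share was 65.2%, 87.2% and 88.9% under the first 3 of these.

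The share of CTR peaks overlapping ORF was 14.5% with reciprocal overlap of 50%, 71.6% with centres within 1000 bp, 27.8% with a −log10 q of at least 5, 9.38% without clusters, and, in added alternatives, 31.0% with a −log10 q of at least 2 and 45.1% without the chromosome 6 segments. The latter holds mitochondrial peaks (22 of 25 overlapping) and scaffold peaks (48 of 83), and on other assembled sequence the share was 35.3%, against 31.0% inside the segments. The share of PSR peaks overlapping ART was 19.9% with reciprocal overlap, 93.1% with a −log10 q of at least 5, 20.95% without clusters and 43.5% with a −log10 q of at least 2. The NC share overlapping ART or PSR was 83.3% for each with a −log10 q of at least 5, and 40.0% (ART) and 45.0% (PSR) with at least 2. The share of merged YBX1 regions overlapping Arteridin was 0% with reciprocal overlap and 1.75% with a −log10 q of at least 5. Its ratio to random placement was 1.83 within 5 kb (added), inside the random range. The ratio fell to 0 for ART against ORF, ART against CTR and PSR against ORF with a −log10 q of at least 5, and for PSR against ORF without clusters. PSR against CTR, already inside the random range, also fell to 0 under both. Random means in these cases were 0.001 to 0.030, so a count of 0 says little. Stricter thresholds, cluster removal and segment removal keep fewer peaks in both lists, reciprocal overlap demands more, and centres within 1000 bp demand less. Beyond this construction the cause was not tested. Over the ratios to random placement, 69 alternatives kept their side of the random range, 12 fell inside it with the ratio still above 1, 1 rose above it, and 4 fell inside it at 0. Not run were the alternatives that needed a genome or annotation: removal of soft-masked peaks and other promoter definitions, gene distances and window sizes for annotation, gene lists and motifs. No paired analysis was possible because each condition had 1 library. The 20 NC peaks whose reads could be recovered had 3 reads each, so such peaks rest on few reads.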

Other observations

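All tests in this part were chosen after the results were seen. In 5 of the 6 YBX1 blocks an Arteridin peak was also listed, and there the expected level at Arteridin summits was far above the background of 0.361 in ORF and 0.349 in CTR. On chromosome 1 from 180644615 to 181077243, the median level over 2 Arteridin peaks was 25.8. ART had 17 peaks there and PSR 10, with median folds of 1.80 and 1.80. On chromosome 13 from 33485613 to 33820432, with 12 ART and 6 PSR peaks, the median over 7 Arteridin peaks was 32.3. The level was 19.7 in the chromosome 14 block at its single Arteridin peak. In the chromosome 6 blocks it was 16.0 at 1 Arteridin peak (30630777 to 30650844) and 11.8 over 2 (31046711 to 31070870). These values describe the sites of those peaks and not whole blocks. The blocks on chromosomes 1 and 13 each hold a region present in all 3 YBX1 lists at low fold.

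The concentration of Arteridin peaks at the start of chromosome 6 was present with and without overexpression. Copies raised at least 2 times in both input and ChIP DNA would raise the input average over 10 kb, which the expected level at a peak cannot be below, but in 73.4% of the 811 bins of 10 kb an ORF peak had an expected level under 2 times the background (61.3% for CTR). The level was under 1.5 times the background in 546 of the 811 bins for ORF and 461 for CTR. Gains in the input below 1.5 times, and gains in the bins without such a peak, are not excluded. Larger gains are not excluded where low mappability reduces the input level, since the level was compared with the genome background. Independent chance rises on an even level would overlap no more than random placement within 5 kb, but ORF peaks overlapped CTR 1.96 times as often as that. Uneven mappability, the input shared by both lists, and a copy gain in the ChIP cells that the input cells lacked remain open, as does Arteridin binding, and no value here decides among them.

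The short NC list may come from the depth of the library, since the background level of ART, which also depends on fragment length, was 7.54 times that of NC. As listed, the NC peaks are not a part of the other lists. Of its 62 peaks with a −log10 q under 2, 1 (1.61%) overlapped ART or PSR, and of its 20 with at least 2, 9 (45.0%) did. These counts were known when the test was chosen, and the weak calls among them cannot show different sites. Of the 6 with at least 5, 5 did (83.3%), and the strongest was the exception. The title letter differs between NC and the overexpression libraries, so a batch and the overexpression cannot be told apart, and an effect of overexpression on YBX1 binding stays open.

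The strongest NC peak, on chromosome 1, was also an Arteridin peak in ORF and CTR. DNA of the overexpression construct carried only by transfected cells would be missing in CTR, where the fold was 15.7. That CTR peak is part of the pattern itself and was known when the prediction was written. Other contaminating DNA and binding by both proteins were not tested, and may each account for the shared peak. The expected level of the NC peak could not be recovered.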
